A study of Mus musculus with 3 samples.

How the data were processed

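RNA-seq of polyadenylated RNA was available for 3 libraries of 1 biosample, numbered technical replicates 1, 2 and 3 per the labels. RNA had been fragmented by shearing, per the labels. All 3 libraries form 1 group, so no groups were compared, and the analyses below describe levels and compare the libraries with one another.

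The authors deposited, per library, a gene table and a transcript table with the column names that RSEM writes, made on the mm10 assembly with GENCODE M21 annotation, per the files that list each library's contents. The aligner, the quantifier's version and the strand setting are not given in the sources used here. The estimated counts (expected counts) in these deposited tables need not be whole, since reads that fit several genes or transcripts are divided among them. The TPM values deposited in the same tables sum to the same fixed total in each file, and the FPKM values deposited there scale fragments to transcript length and depth. The median of length minus effective length was 49 in the deposited gene table of replicate 1. A second, smaller deposited table per library holds whole-number counts for 22457 genes of GENCODE M4, with no statement of how reads were counted or whether duplicates were removed.

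The larger gene table has 81881 rows: 55536 genes, 96 spike-in rows, 1 phiX row and 26248 numbered rows that name no gene. Rows that name no gene were left out of library totals and tests; phiX took 0.224, 0.262 and 0.182% of all counts in replicates 1, 2 and 3, and the spike-in rows had none. Symbols and 1-based coordinates came from GENCODE M21, which names 55450 of the genes. Where a symbol belongs to several genes, the gene with the highest mean count was taken. Depth was 20783676, 21206219 and 18496690 estimated counts in replicates 1, 2 and 3, so that 3 counts, the limit that a count of 0 allows, correspond to 0.144, 0.141 and 0.162 CPM, counts scaled to library size. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

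Levels are means of deposited TPM with the SD over 3 libraries. Detection meant 1 TPM or more in every library. There were 18 gene lists and 8 lists of cell type markers. Each list's median was set against 10000 random lists of the same size from 21951 protein-coding genes, and differences between list medians used log2(TPM + 0.1) per library. Differences between libraries were tested per gene with Pearson's chi-square test of homogeneity (2 degrees of freedom) on estimated counts rounded to whole numbers against library totals, for genes with a summed count of 30 or more, with Benjamini-Hochberg adjustment. The common coefficient of variation came from edgeR's estimateDisp on rounded estimated counts with an intercept, TMM factors and filterByExpr. For shares of transcripts, 12 genes were taken.

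Named genes were chosen by rule: all members of lists of up to 8 genes, otherwise the 4 highest and 2 lowest by mean TPM; a fixed set of identity, sex-linked and reporter-related genes; the 15 most abundant genes other than mitochondrial and ribosomal protein genes; the 5 genes with the largest ratio between libraries among those that differed with a mean count of 100 or more; and the 5 highest Trbv genes. Hspa1b among the library differences, and the genes Hspa8, Ighg2c, Cd109, Slc15a2 and Xlr3b, were named after their values were seen. Some genes that the rule names are not reported here; they stay in every count and list median. The groups, lists, naming rule, processing alternatives and the tests behind the report were fixed before the data were examined; this does not hold for every test of an explanation in the closing section.

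The alternatives were other TPM thresholds, the mean in place of every library, FPKM, TMM and DESeq2 scaling, other count filters, a deviance statistic, other pseudocounts, list means, the second gene table, transcript estimated counts, DESeq2's dispersion and leaving out each library in turn. The library test was tested on simulated counts drawn from the means and sizes of these 3 libraries over 14641 genes, with 200 genes changed in 1 library. It recovered 72% of genes changed 1.25-fold, 92% of those changed 1.5-fold, and 100% of those changed 2-fold or 3-fold, and called 0.512% of unchanged genes. The changed genes were drawn from those with a mean count of 100 or more, and the simulated counts held counting noise alone. These rates therefore do not cover changed genes with lower counts or duplicated reads. On counts simulated with a coefficient of variation of 0.1, edgeR returned 0.0994. On counts simulated with a GC and length trend, the binned correction lowered the calls from 6110 to 122. Software was R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.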

Results

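Polyadenylated RNA was profiled by RNA-seq in primary mouse cells annotated as activated regulatory T cells. Regulatory T cells are CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3. The cells came from a male animal of 9 weeks whose strain name lists Foxp3GFP-DTR, CD4CreERT2 and R26tdTomato alleles. There was 1 group of 3 libraries, recorded as technical replicates 1, 2 and 3 of 1 biological replicate. Gene-level estimated counts totalled 20783676 in replicate 1, 21206219 in replicate 2 and 18496690 in replicate 3. No resting, untreated or other cell population was part of the group, so levels are described and no contrast between conditions was made. Every SD below is taken over these 3 libraries (n = 3), and both the SDs and the p-values measure only the spread between libraries of 1 biosample, which may be technical.

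The genes of the regulatory T cell programme were abundant. Foxp3 itself, the lineage-defining factor, was at 90.1 ± 6.76 TPM (SD, n = 3). Il2ra, the alpha chain of the interleukin-2 receptor, was at 352 ± 41.0 TPM, and Ctla4, an inhibitory receptor, at 319 ± 5.43 TPM. The highest members of the regulatory T cell core list were Izumo1r (970 ± 28.6 TPM), the interleukin-2 receptor beta chain Il2rb (918 ± 89.0 TPM), Tnfrsf18 (734 ± 55.8 TPM) and Capg (564 ± 28.4 TPM). Its lowest members were Entpd1 (46.0 ± 1.04 TPM), an ectoenzyme that degrades extracellular ATP, and the zinc finger gene Plagl1 (9.66 ± 2.19 TPM). All 18 members reached 1 TPM in every library and 12 had a mean of 100 TPM or more. The median of the list was 213 ± 17.4 TPM, above every one of 10000 random protein-coding lists of that size. Foxp3 (ENSMUSG00000039521.13) lies on chromosome X at 7573644 to 7595245, Il2ra (ENSMUSG00000026770.5) on chromosome 2 at 11642807 to 11693193 and Ctla4 (ENSMUSG00000026011.13) on chromosome 1 at 60887000 to 60915832 of mm10.

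Cytokines of conventional helper T cells were mostly near or below detection. Tnf was the highest of the 13 measured, at 45.3 ± 0.935 TPM. Il21 followed at 26.6 ± 13.5 TPM, with 34.4 TPM in replicate 1, 11.0 TPM in replicate 2 and 34.3 TPM in replicate 3. Ifng was at 13.5 ± 4.49 TPM and Il4 at 4.33 ± 0.552 TPM. The remaining members were low, and 5 of the 13 had no count in any library, among them Il9 and Il17a. A count of 0 allows up to 0.144, 0.141 and 0.162 CPM (counts scaled to library size) in replicates 1, 2 and 3, for counting error only. The median of the regulatory T cell core list exceeded that of the helper cytokines by 10.59 ± 0.91 on the log2(TPM + 0.1) scale. The size of this gap depended on the undetected cytokines: it was 4.02 when members under 1 TPM in every library were left out.

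**Figure D1:**
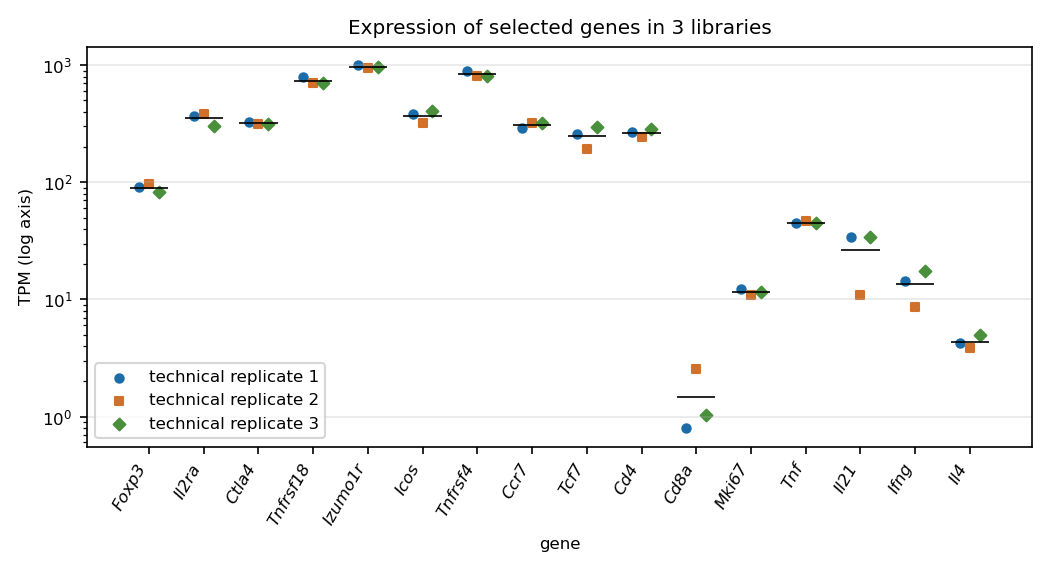
TPM of selected genes (log axis) in the 3 libraries; each point is a library, each horizontal line the mean. Foxp3 lies near 90.1 TPM and Il2ra near 352 TPM, while Il4 lies near 4.33 TPM and Il21 is lowest in replicate 2.

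Genes linked to activated and effector regulatory T cells and genes of resting T cells were both expressed. RNA pooled over cells does not show whether the same cells expressed both. In the activated list, Tnfrsf4 (842 ± 43.5 TPM), S100a6 (475 ± 84.7 TPM), the costimulatory receptor Icos (372 ± 44.3 TPM) and S100a4 (351 ± 20.01 TPM) were highest. Havcr2 (3.67 ± 1.10 TPM) and the growth factor Areg (2.05 ± 0.871 TPM) were lowest, and all 25 members reached 1 TPM in every library. In the resting list, the migration receptors Ccr7 (310 ± 15.4 TPM) and S1pr1 (271 ± 14.8 TPM) were high, with Foxp1 at 264 ± 4.99 TPM. Dapl1 (13.2 ± 2.90 TPM) and the transcription factor Klf2 (9.76 ± 0.612 TPM) were its lowest members, and Tcf7, a factor of naive and memory T cells, was at 250 ± 53.1 TPM. The list medians were 65.5 ± 2.06 TPM for the activated list and 142 ± 15.3 TPM for the resting list. Their difference, activated minus resting, was -1.11 ± 0.12 on the log2(TPM + 0.1) scale, a gap larger than the spread between libraries. It sets different genes side by side and carries no information about a change on activation. With the mean of each list in place of the median it was -0.38.

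T cell identity genes dominated the lists. All 17 had a mean of 100 TPM or more and their median was 894 ± 30.3 TPM. Trbc2 and Trbc1, the T cell receptor beta constant genes, were at 4012 ± 176 and 1937 ± 80.2 TPM. The alpha constant gene Trac was at 3180 ± 250 TPM and the kinase Lck at 1491 ± 121 TPM. Cd28 (192 ± 10.8 TPM) and Thy1 (110 ± 15.5 TPM) were lowest. Trbc1 and Trbc2 are near-identical, so their separate values are uncertain. Cd4 stood at 264 ± 20.6 TPM and Cd8a at 1.46 ± 0.960 TPM. All 22 annotated Trbv genes had 3 or more summed counts, and 21 had 30 or more. This describes the use of beta variable genes and not the number of clones. By TPM, Trbv13-2 (355 ± 32.2), Trbv3 (259 ± 23.5), Trbv12-1 (200.3 ± 8.95), Trbv12-2 (179 ± 38.7) and Trbv16 (178 ± 18.6) led, and the gene with the most reads held 11.5% of Trbv reads.

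Other immune lists ranged widely. Among the 8 helper lineage factors, Gata3 was highest at 107 ± 2.99 TPM, followed by Zbtb7b (58.8 ± 2.28 TPM), Rora (53.2 ± 6.01 TPM) and Bcl6 (25.8 ± 4.21 TPM). Tbx21 was at 11.0 ± 4.01 TPM, Runx3 at 7.50 ± 1.21 TPM and Eomes at 1.71 ± 0.318 TPM. The chemokine receptor list was led by Ccr7, Cxcr3 (260.0 ± 43.2 TPM), Cxcr5 (135 ± 27.2 TPM) and Ccr8 (90.5 ± 12.6 TPM), while Cxcr1 and Cxcr2 were at 0.0267 TPM each. In the TNF receptor family, Cd27 (571 ± 11.9 TPM) and Tnfrsf1b (366 ± 20.4 TPM) followed Tnfrsf4 and Tnfrsf18, and Cd40 and Ltbr were at 1.31 and 0.233 TPM. The inhibitory and suppressive list was led by Lgals1 (650.2 ± 46.8 TPM), Ctla4, the checkpoint receptor Pdcd1 (232 ± 54.6 TPM) and Vsir (230.0 ± 8.72 TPM), and Il12a was at 0.0467 TPM. In the list named Foxp3 partners, Ets1 (413 ± 54.0 TPM), Stat3 (264 ± 15.6 TPM), Nfatc1 (156 ± 12.5 TPM) and Stat5b (143 ± 3.59 TPM) were highest. Hdac9 (3.91 ± 1.35 TPM) and Foxo3 (1.72 ± 0.293 TPM) were lowest there. How each member relates to Foxp3 was not tested. In the interferon list, Bst2 was at 163 ± 2.67 TPM, Usp18 at 134 ± 2.30 TPM and Irf7 at 97.5 ± 7.04 TPM. Rsad2 and Ifi44 were at 5.90 and 5.77 TPM. The list medians were 18.6 ± 3.86 TPM for the lineage factors, 13.8 ± 0.641 for the chemokine receptors, 96.9 ± 7.35 for the TNF receptor family, 62.0 ± 3.17 for the inhibitory list, 41.9 ± 3.60 for the Foxp3 partners and 43.6 ± 4.48 for the interferon list.

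Metabolic and growth lists lay above most random lists. Glycolytic genes had a median of 215 ± 29.4 TPM, led by lactate dehydrogenase Ldha (1195 ± 74.2 TPM), Eno1 (1101 ± 90.4 TPM), Pkm (1002 ± 114 TPM) and Aldoa (629 ± 76.9 TPM). Slc2a1, a glucose transporter, was at 50.2 ± 0.935 TPM and Hk2 at 3.15 ± 0.250 TPM. The fatty acid oxidation list had a median of 44.0 ± 0.311 TPM with Hadhb (178 ± 8.37 TPM), Etfb (135 ± 8.79 TPM), Etfa (110 ± 10.3 TPM) and Acadvl (106 ± 6.95 TPM) highest, and Ppargc1a and Ppara at 0.167 and 0.0633 TPM. The cholesterol synthesis list had a median of 36.7 ± 2.25 TPM, with Srebf2 at 144 ± 4.95 TPM, Fdps at 76.3 ± 6.34 TPM and Sc5d at 74.4 ± 1.72 TPM. Insig1 was at 9.61 ± 2.57 TPM. Proliferation genes had a median of 33.6 ± 8.69 TPM. Mcm6 (154 ± 36.8 TPM), Pcna (148 ± 4.18 TPM), Cenpa (104 ± 13.3 TPM) and Mcm2 (73.8 ± 7.36 TPM) were highest, Ccna2 (4.61 ± 2.25 TPM) and Bub1 (4.09 ± 1.68 TPM) lowest, and Mki67, a proliferation marker, was at 11.6 ± 0.666 TPM. Among immediate early and stress genes, Junb (448 ± 99.6 TPM), Hsp90aa1 (331 ± 48.4 TPM), Zfp36 (195 ± 2.68 TPM) and Ier2 (126 ± 27.0 TPM) were highest, and Fosb and Atf3 were at 0.700 and 0.0933 TPM. The median of that list, 17.5 ± 4.78 TPM, lay at the 97.6 percentile of random lists, at 96.5 without replicate 1 and at 97.2 without replicate 2. In all, the medians of 14 of the 26 lists lay above the 97.5 percentile of random lists. The random lists draw on 21951 protein-coding genes, of which 10415 reached 1 TPM in every library. A list of expressed genes therefore lies high among them, and the percentiles do not show raised levels. The erythroid marker list lay at the 99.99 percentile.

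**Figure D2:**
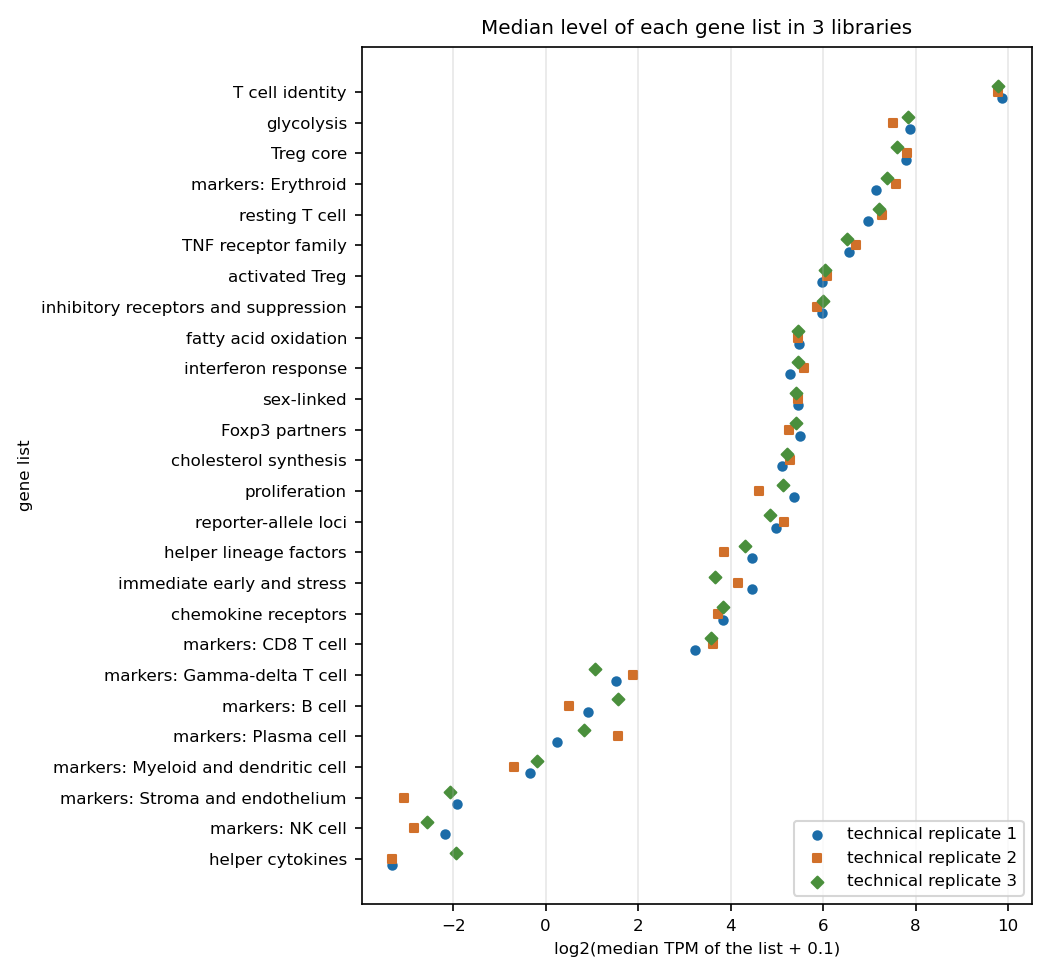
Median of each gene list, as log2(median TPM + 0.1), in each library; points are technical replicates 1, 2 and 3. Averaged over the libraries, T cell identity genes are highest, with a median of 894 TPM, and helper cytokines lowest; in replicate 3 the NK cell and stromal lists lie below the cytokines.

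Markers of other cell types were low with some exceptions. The B cell list had a median of 1.98 ± 0.796 TPM, with Cd79b at 38.7 ± 0.981, Cd22 at 14.9 ± 2.39, Cd79a at 6.61 ± 1.32, Ms4a1 at 2.19 ± 1.07, Blnk at 1.10 ± 0.243, Ebf1 at 0.683 ± 0.233 and Pax5 at 0.597 ± 0.222 TPM. In the plasma cell list, Ighm, the immunoglobulin mu heavy chain, was at 1624 ± 106 TPM and Igkc, the kappa light chain, at 175 ± 109 TPM, whereas Jchain was at 2.90 ± 1.49, Igha at 0.833 ± 0.356 and Sdc1 at 0.347 ± 0.176 TPM, and Tnfrsf17 had no count. Erythroid globins were present: Hba-a2 stood at 391 ± 54.9, Hbb-bs at 379 ± 78.4, Hba-a1 at 253 ± 41.7 and Hbb-bt at 78.9 ± 7.53 TPM, with Alas2 at 6.80 ± 2.31 TPM. The globin copies share reads, so the split within each pair is uncertain. Cd8b1 was at 20.6 ± 2.57 TPM although Cd8a was low. The myeloid and dendritic list had a median of 0.668 ± 0.132 TPM, with Lyz2 at 15.03 ± 2.04, Csf1r at 8.09 ± 2.28, Adgre1 at 3.41 ± 1.43, Itgam at 1.10 ± 0.0416 and Flt3 at 0.0900 TPM, and S100a8 had no count. NK cell genes had a median of 0.0767 ± 0.0404 TPM. Among them Klrb1c was at 2.32 ± 0.637 and Klre1, Klra4, Ncr1 and Klra8 were at 0.0733, 0.0433, 0.0367 and 0.0233 TPM. Gamma-delta T cell genes had a median of 2.80 ± 0.815 TPM, with Tcrg-C4 at 4.52 ± 0.363, Tcrg-C1 at 4.42 ± 1.06, Tcrg-C2 at 2.60 ± 1.13 and Trdc at 2.13 ± 0.396 TPM, and Sox13 had no count. In the stromal and endothelial list, whose median was 0.108 ± 0.0775 TPM, Pecam1 alone exceeded 10 TPM, at 97.1 ± 6.61 TPM. Col1a2, Col1a1, Col3a1, Kdr and Cdh5 were at 0.387, 0.340, 0.153, 0.0600 and 0.0267 TPM, and Pdgfra and Pdgfrb had no count. The medians of the plasma cell, erythroid and CD8 T cell lists were 1.87 ± 0.906, 166 ± 24.6 and 11.05 ± 1.57 TPM.

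The sex-linked list had a median of 43.6 ± 0.695 TPM. Of its Y chromosome genes, Eif2s3y was at 110 ± 5.28, Ddx3y at 90.3 ± 11.7, Kdm5d at 42.8 ± 0.906 and Uty at 42.8 ± 1.43 TPM, while Xist, the long RNA of the inactive X chromosome, was at 0.117 ± 0.0971 TPM. The loci related to the alleles in the strain name had a median of 31.9 ± 3.45 TPM, the level of Gt(ROSA)26Sor. Esr1, the oestrogen receptor gene, was at 1.88 ± 0.408 TPM and Hbegf, the mouse counterpart of the diphtheria toxin receptor, at 1.57 ± 0.414 TPM. Esr1 had 68, 44 and 32 estimated counts in replicates 1, 2 and 3 but 171, 163 and 168 counts in the second gene table, and Hbegf 55, 61 and 21 against 99, 96 and 79, although that table holds 30.3, 29.3 and 31.1% as many counts in all. The levels of both genes are therefore uncertain. These values come from the mouse reference genes and say nothing direct about the inserted sequences.

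Across all genes, 12598 reached 1 TPM in every library, of which 10415 were protein-coding. The most abundant, leaving aside mitochondrial transcripts and ribosomal proteins, were Tmsb4x (15851 ± 454 TPM), H2-K1 (11006 ± 324 TPM), the ribosomal RNA gene CT010467.1 (9215 ± 486 TPM), B2m (7890 ± 158 TPM) and H2-D1 (5711 ± 246 TPM). Gm37376 (4707 ± 518), Actb (4367 ± 342), Shisa5 (4129 ± 205), Tmsb10 (4075 ± 84.8), Trbc2, Gm29216 (3990 ± 126), Eef1a1 (3987 ± 425), Pfn1 (3957 ± 717), Ppia (3664 ± 60.5) and the long RNA Malat1 (3630 ± 379) followed, all in TPM. H2-K1 and H2-D1 belong to a multigene family and Gm29216 is an annotated pseudogene, so their values are uncertain. Gm37376 (chromosome 19, 5801941 to 5802393) lies on the opposite strand within the span of Malat1 (5795690 to 5802672). The strand setting is not given, so the split of reads between Gm37376 and Malat1 is uncertain too.

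The 3 libraries were compared with one another to ask whether they differ by more than counting noise. Hspa1b, an inducible heat shock chaperone, was at 9.86 CPM in replicate 1, 79.7 in replicate 2 and 7.95 in replicate 3, and its near-identical neighbour Hspa1a at 0.866, 20.7 and 1.41. All 20 proliferation genes were lowest in replicate 2 and 19 were highest in replicate 1, under library totals as well as TMM and DESeq2 scaling; 19 of the 20 differed between libraries, and 19 did when adjusted over the list alone. Replicate 2 also had the highest shares of mitochondrial, ribosomal protein and ribosomal RNA counts. The mitochondrial share was 1.62, 1.79 and 1.498% in replicates 1, 2 and 3, the ribosomal protein share 2.59, 3.22 and 2.72%, and the ribosomal RNA share 0.981, 1.12 and 1.05%, with 95% Wilson bounds at most 0.00752 percentage points away. Of the cholesterol synthesis genes, 10 of 12 were highest in replicate 2 under each of these scalings, 10 differed and 10 did when adjusted over the list alone. Of the regulatory T cell core genes, 16 of 18 were lowest in replicate 3 under each scaling and 16 differed, with 16 adjusted over the list alone. Highest in replicate 3 under each scaling were 6 of 8 B cell markers, 6 of 11 myeloid and dendritic markers with counts and 6 of 8 helper cytokines with counts. Of the B cell markers 3 of 8 differed, and of the myeloid and dendritic markers 3 of 7 tested. Highest in replicate 1 were 4 of 6 NK cell and 4 of 6 stromal markers with counts, but most of these rest on few reads. Klra4, Klra8 and Ncr1 had 2, 1 and 2 summed counts, and Cdh5, Col3a1 and Kdr 4, 8 and 13. Of the NK cell markers 0 of 2 tested differed, and of the stromal markers 1 of 3. That stromal marker was Pecam1, which was highest in replicate 3. Of the activated list 19 of 25 differed (19 adjusted over the list alone), and of the resting list 8 of 15 (11 adjusted over the list alone). Of all genes tested, 44.9% differed, and of those with a mean count of 100 or more, 5512 of 9956 did. List counts near these shares do not set a list apart. The test finds smaller differences in genes with more counts: Cd3e differed at a ratio of 1.03 between the highest and lowest library. These shares were not matched to the counts of each list. List counts above them may therefore reflect abundance, and by themselves do not set a list apart either. Among the other lists, the test found differences in 14 of 17 T cell identity genes (15 adjusted over the list alone), 11 of 14 glycolysis genes (11), 19 of 20 Foxp3 partners (19), 15 of 16 stress genes tested (15) and 11 of 16 inhibitory genes tested (11). It found them in 7 of 8 lineage factors (8 adjusted over the list alone), 8 of 11 interferon genes (8), 10 of 15 chemokine receptors tested (10), 9 of 12 TNF receptor genes tested (10) and 7 of 10 fatty acid oxidation genes tested (7). Differences were found in 2 of 5 cytokines tested, 2 of 4 sex-linked genes tested and all 5 reporter-related loci, with the same counts adjusted over the list alone. Of these loci, Esr1 had 171, 163 and 168 counts in replicates 1, 2 and 3 of the second gene table, and Hbegf 99, 96 and 79. The differences of Esr1 and Hbegf are therefore uncertain. All 6 erythroid markers were highest in replicate 2 and 5 of them differed (5 adjusted over the list alone). In that library the immunoglobulin kappa gene Igkc was also highest, at 298 TPM against 88.7 in replicate 1 and 138 in replicate 3.

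**Figure D3:**
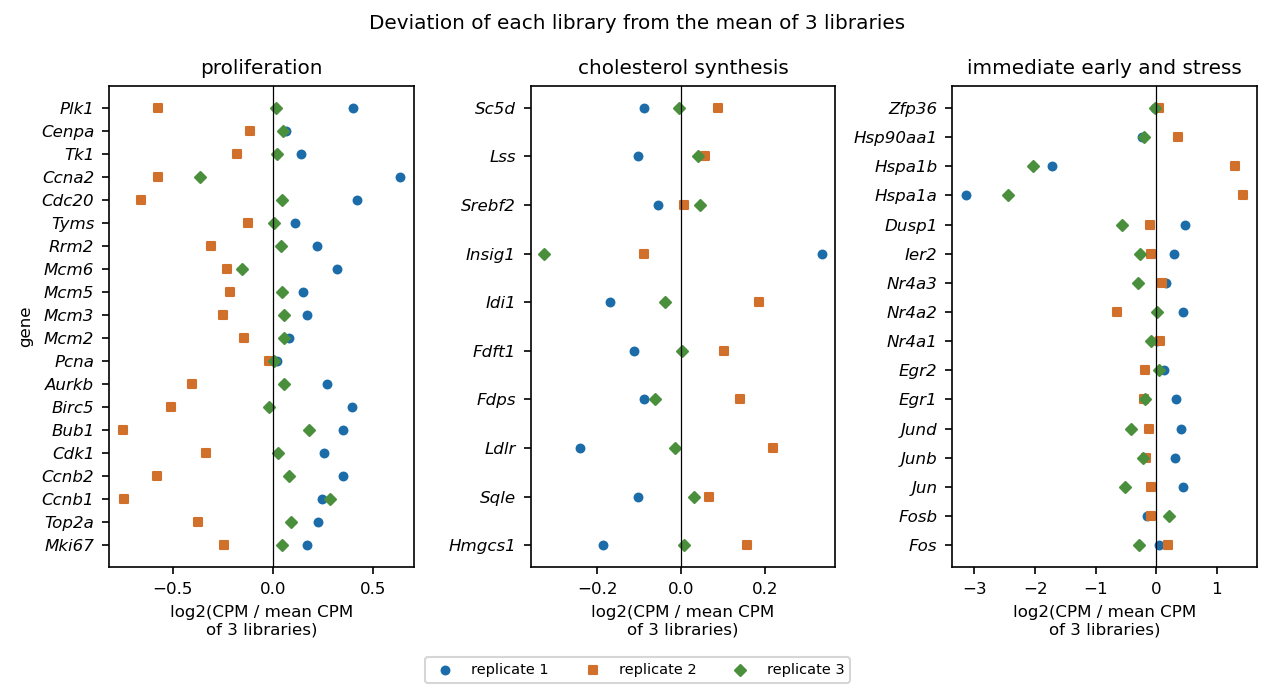
log2 ratio of each library's CPM to the mean of the 3 libraries for members of 3 lists with at least 30 summed counts, some cholesterol synthesis genes not shown; each point is a gene in a library. All 20 proliferation genes are lowest in replicate 2, and Hspa1a and Hspa1b are highest there.

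In total, 6575 of 14641 genes tested (44.9%) differed between the libraries (Pearson chi-square test of homogeneity, Benjamini-Hochberg adjusted p under 0.05). Among genes that differed and had counts in every library, the median ratio of the highest to the lowest library was 1.27, and 1689 exceeded a ratio of 1.5 and 742 a ratio of 2. With a mean count of 100 or more, 5512 of 9956 genes differed, of which 726 exceeded a ratio of 1.5 and 117 a ratio of 2. The genes with the largest ratios had no count in a library after rounding: the pseudogenes Gm6565 (205, 0.02 and 151 estimated counts in replicates 1, 2 and 3) and Rpl9-ps4 (0, 218 and 137), the T cell receptor gene Trav7d-2 (340, 0 and 309) and the kappa variable gene Igkv1-135 (0, 371 and 4). Pseudogenes and Trav genes share reads with close copies, so the values of the first 3 are uncertain. Genes that differed numbered 4157 (30.3% of those tested) without replicate 1 and 3782 (27.7%) without replicate 2, where fewer libraries entered the test, and 2520 (23.2%) in the second gene table. The share depends on the filter: with every gene above 0 counts tested it was 20.1%, or 6276 of 31194. The common coefficient of variation between libraries beyond counting noise was 0.115 by edgeR, and 0.0597 as the square root of the median gene-wise dispersion of DESeq2.

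Transcript shares were steady in some genes and divided in others. The leading transcript held over 50% of the gene's transcript TPM in 11 of 12 genes examined. Without replicate 3 the count was 10, as Foxp3-207 held 45.7 and 51.3% of Foxp3 in replicates 1 and 2. Ctla4-201 carried 99.4 ± 0.271% of Ctla4, Tcf7-201 96.6 ± 1.32% of Tcf7 and Pkm-201 92.1 ± 1.71% of Pkm. Bcl2l1-201 carried 74.2 ± 1.75%, Il2ra-201 71.9 ± 0.904%, Il1rl1-201 70.9 ± 8.91%, Icos-202 56.0 ± 1.05% and Cd44-203 55.7 ± 4.64% of their genes. Ptprc, which encodes CD45, was divided, with Ptprc-203 at 40.5 ± 1.32% and Ptprc-204 at 19.2 ± 0.711%. Some leading transcripts are not annotated as coding: Foxp3-207 (51.5 ± 5.88%) and Ikzf4-208 (55.4 ± 1.40%) are listed as targets of nonsense-mediated decay, and Ikzf2-205 (67.6 ± 1.10%) as a retained intron. By estimated counts instead of TPM, Foxp3-207 still led but held 46.5% of Foxp3, Ikzf2-205 40.5% and the coding Ikzf2-201 50.5% of Ikzf2. The leading transcript of Cd44 also changed, with Cd44-203 at 42.6% and Cd44-207 at 54.5%, so the leading transcript of Ikzf2 and Cd44 depends on the unit. Icos-202 still led, at 84.2% of Icos. Ptprc-203 held 50.2% of Ptprc by estimated counts, so 11 of 12 genes again passed 50%, with Ptprc among them and Foxp3 not. Reads are divided among overlapping transcripts by a model, so these shares are estimates.

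**Figure D4:**
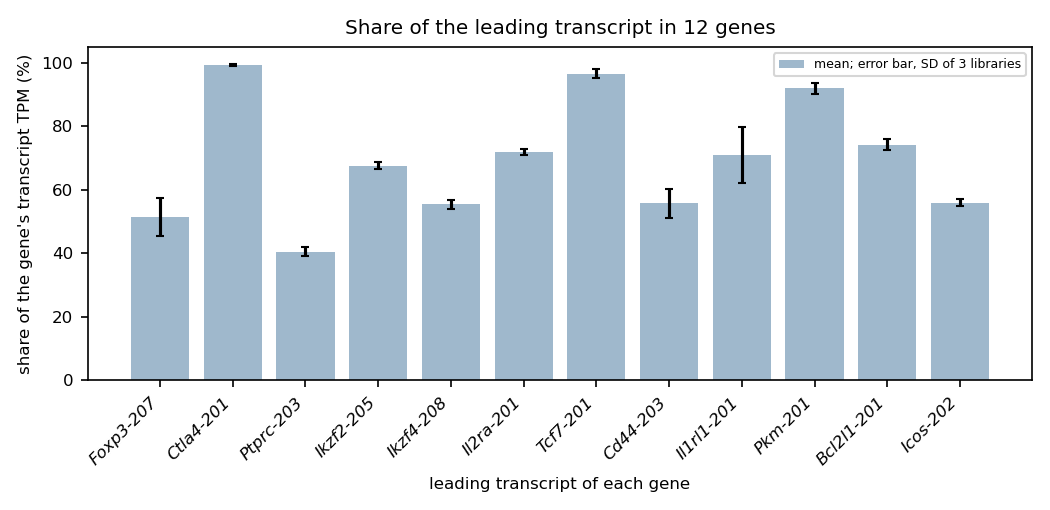
Share of each gene's summed transcript TPM (percent) held by its leading transcript; bars are means and error bars the SD of 3 libraries. Ctla4-201 is highest at 99.4% and Ptprc-203 lowest at 40.5%.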

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

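Reads outside the comparisons stood above the 3 counts that a count of 0 allows in every library. The phiX row, a sequencing control, held 46649 reads in replicate 1, 55677 in replicate 2 and 33785 in replicate 3. These are 0.224% (95% Wilson interval 0.222 to 0.226), 0.262% (0.260 to 0.264) and 0.182% (0.180 to 0.184) of all counts. The numbered rows that name no gene held 1374, 1845 and 1329 reads in replicates 1, 2 and 3.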

How the results depend on the processing

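All alternatives were fixed before the data were examined. Counts of detected genes, of lists above the 97.5 percentile and of genes with a leading transcript over 50% stayed within 1.5 times their reported values under every alternative run, and no difference between lists changed sign. The count of genes that differed between libraries was 2520 of 10885 tested in the second gene table, which differs in annotation, reads counted and genes tested, so the cause was not isolated, and between 3782 and 4700 with a library left out, where the test had fewer libraries; the counts under the other alternatives stayed within 1.5 times. As a share of genes tested, it was 20.1% without a count filter, where more low genes were tested, against 44.9%. The coefficient of variation was 0.127 without a filter on low counts, 0.0822 in the second gene table and 0.0597 from DESeq2's gene-wise dispersions; the cause was not tested. The gap between the regulatory T cell core and helper cytokine lists was 7.66 with a pseudocount of 1 and 13.01 with 0.01, as undetected cytokines sit at the pseudocount, 4.02 without members under 1 TPM in every library, where fewer genes entered, and 8.10 with list means. The difference of the activated and resting lists was -0.38 with list means. It was -0.75 in the second gene table, where the unit was log2(CPM + 0.1), not scaled to gene length. The cause of either change was not tested. Depth limits the low genes: a gene without counts may still lie below 0.162 CPM.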

Other observations

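The tests of the Igkc to Ighm ratio and all tests of the second gene table were chosen after the values were seen; the other tests were set beforehand. Several single genes differed between the libraries beyond the lists. Slc15a2, a gene of a peptide transporter, was at 9.37, 2.68 and 13.0 TPM in replicates 1, 2 and 3, and Cd109, which encodes a surface protein, at 3.05, 0.300 and 1.78 TPM. Xlr3b, on the X chromosome, was at 37.2, 11.7 and 4.48 TPM. Its estimated counts, 1031.28, 330.89 and 106.28 in replicates 1, 2 and 3, were not whole. The second gene table held 20, 6 and 3 counts, in the same order, so its level is uncertain. Ighg2c, an immunoglobulin heavy chain constant gene, was at 1.89, 2.37 and 19.98 TPM. Hspa8, a constitutive heat shock chaperone, was at 1920 TPM in replicate 1, 2860 in replicate 2 and 2145 in replicate 3, moving with the inducible Hspa1a and Hspa1b.

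The libraries, recorded as technical replicates of 1 biosample, differed by more than counting noise. GC content and length do not account for it: 6570 genes passed the threshold before correction in bins of both and 6393 after it, 5937 of them in both counts. Sharing of reads between paralogs does not either: of 7541 genes whose estimated counts were whole within 0.005 in every library, taken as a sign that no read was divided with another gene, 42.1% differed, against 44.9% of all. A candidate explanation is that the libraries hold separate samples of cells. T cell receptor variable genes differ in use between clones, though a variable gene alone does not identify a clone. The 121 tested had a median chi-square of 2.92 per degree of freedom, above 99.2% of count-matched gene sets (median 2.14). The 21 of them with whole counts by that tolerance had a median above 96.4% of matched whole-count sets. Among the variable genes tested, 39 of 100 Trav and 12 of 21 Trbv genes differed, against 44.9% of all genes. Both percentile tests could have come out the other way. The percentiles do not tell separate cells from separate animals, and uneven amplification remains untested.

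Ighm stood at 1624 TPM although B cell markers were low. RNA of B cells or plasma cells does not account for it: heavy-chain variable genes had 0.197 reads per 100 Ighm reads, while beta variable genes had 23.9 reads per 100 Trbc reads and kappa variable genes 31.4 per 100 Igkc reads. The ratio of Igkc to Ighm varied 3.79-fold between libraries, which speaks against a single source for both. A hypothesis left open is that the Ighm reads come from transcripts without a rearranged variable segment, as T cells may make from the unrearranged locus; the design has no group that tests it.

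The second gene table levelled off at abundant genes. Its median ratio to the larger table was 0.529 in the sixth of 10 classes of read density and 0.234 in the highest. A cap of 1 count per start position and strand is a candidate explanation: 0% of the 1184 genes in the highest class passed 2 counts per exonic base, the maximum being 1.91, while the larger table reached 98.5. Counting of uniquely placed reads does not account for all of it, since 68.8% of genes with whole counts in the highest class lay below the lower quartile of the middle class. As a part of the cause it stays open, because the median ratio there was 0.548 of that in the middle class, between the bounds set for either outcome.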
